A study of Mus musculus with 9 samples.

How the data were processed

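Neural retina was taken from mouse pups at postnatal day 4 (P4) that either lacked Opn4, the gene of the photopigment melanopsin, on both chromosomes or were wildtype. Per the labels, pups of both genotypes were littermates of crosses between Opn4 heterozygotes, were raised under about 300 lux, and were killed between 6 and 7 h after lights on (ZT6 to ZT7). Each sample was a pool of 4 retinas from 2 animals of 1 genotype, and the pools of a genotype therefore came from separate animals. There were 5 knockout pools and 4 wildtype pools, each sequenced as 1 poly-A RNA library with paired reads of 150 bases, from RNA of more than 500 ng and an RNA integrity number above 8.5. The labels give neither the sex of the pups, the litters that went into a pool, the part of Opn4 that the allele removes, nor the strain in which it was made.

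The authors deposited 3 tables. The first holds whole-number counts per gene symbol, unnormalised, with 53280 genes and no row without a gene name, and the program that wrote these deposited counts is not given in the sources used here. Its totals of 65.5 M to 86.1 M per pool (M, mega) exceed the 42.7 ± 3.9 M reads per sample that the submitters state. The mitochondrial gene mt-Co3 and its nuclear copy Gm28437 had near-equal counts in every pool, with a ratio of 0.991 to 0.998. Whether reads that match several places were credited to each, shared between them or placed at random is not given in the sources used here. A difference at a gene with a near-identical copy is therefore uncertain as to which copy it belongs to. Gene names that spreadsheet software had turned into dates stood in 24 rows and were kept as they were.

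The second table holds TPM (transcript abundance scaled by transcript length and sample total) from kallisto 0.46.1 on GRCm38 after trimming with Trimmomatic 0.39, per the submitters' processing notes. These deposited TPM values are listed per transcript, with 118489 rows but no transcript identifiers, and their column sums of 953963 to 1083977 show that they were rescaled between samples by the authors in a way the sources used here do not describe. Of these rows, 1673 carried no gene symbol and held 0.612 to 0.833% of the TPM of a pool, and 188 carried a symbol of digits alone. Both kinds were left out of tests. The third table is the authors' deposited comparison of both genotypes per gene, made with sleuth 0.30.8 per the submitters' processing notes. It gives p-values and q-values per the file headers, and its effect b is on the natural log scale with positive values higher in wildtype, which was read from the deposited values of Opn4 and from the TPM. The effects were converted here to log2 with knockout minus wildtype.

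The main test was run on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and genotype was tested with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A log2 fold change is knockout minus wildtype throughout, and levels are CPM (counts scaled to library size) as mean ± SD over 5 knockout and 4 wildtype pools. Opn4 was also tested by an exact two-sided permutation test over the 126 ways to choose 4 of 9 pools. On simulated counts for the 21150 genes of this comparison, the test recovered 65% of genes changed by 1.5-fold, 64.4% of those changed by 2-fold and 86.6% of those changed by 3-fold, and called 7 of 20950 unchanged genes.

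Before the data were examined, 30 gene lists were written for retinal cell types, signalling pathways, tissues next to the retina, blood, sex-linked genes and the neighbours of Opn4. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 30 lists. Camera with an estimated correlation and fry were run beside it. The level of a list in a pool is the mean log2 CPM of its genes relative to the mean of all pools. Transcripts with a TPM of at least 1 in at least 4 pools were tested with limma-trend on log2(TPM + 0.5), a scale that understates the change of low transcripts. On simulated data, that test recovered 73 of 200 transcripts raised by 2-fold. Positions came from GENCODE M21 on GRCm38, in which 96.9% of the gene symbols of the count table were found exactly once. The share of called genes near Opn4 was compared with that of all other tested genes by Fisher's exact test, two-sided. Near-identical copies were searched among GENCODE M21 transcripts with BLAST 2.17.0 (megablast), as matches of at least 95% identity over at least 50% of a transcript. Windows of the width of that around Opn4 were also laid every 10 Mb over the other autosomes and the X chromosome, where they held at least 100 tested genes.

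The rule for named genes was also written before the data were examined. After Opn4, it took the 12 called genes with the largest change in each direction among those with a mean CPM of at least 1 and no overlap between the genotypes, leaving out predicted genes and pseudogenes. It then took up to 4 members of each list by smallest p, and the 6 genes of smallest q in each direction of the authors' table. Genes named outside this rule are said to be so, and a few genes are not reported here. Alternatives covered the scaling, the filter, the test, the threshold, a block for the sample number, each pool left out in turn, 1 surrogate variable (sva 3.50.0), the mean of Y-linked genes as a covariate, DESeq2 1.42.0 and gene-summed TPM. Alternatives added after seeing the data left out knockout pools 1 and 2, wildtype pool 3 or chromosome 14, or kept protein-coding genes alone, or ran camera on the gene-summed TPM.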

Results

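The series title asks how melanopsin-expressing ganglion cells (ipRGCs, retinal output neurons that are themselves light sensitive) control the number of rod photoreceptors during development. The data answer a narrower question: which transcripts of the whole neural retina differ at P4 between Opn4 knockout and wildtype littermates. At this age the mouse retina still holds dividing progenitors, and rods and bipolar cells are among the last cell types to form. The count table held 76.2 M, 77.4 M, 65.5 M, 74.7 M and 86.1 M counts in knockout pools 1 to 5, and 85.9 M, 73.4 M, 82.5 M and 80.4 M in wildtype pools 1 to 4, with no difference in totals between the genotypes (exact permutation p = 0.333). Mitochondrial transcripts took 3.37 ± 0.10% of counts in knockout and 3.19 ± 0.11% in wildtype (exact permutation p = 0.0476). Log2 CPM correlated across genes at 0.981 to 0.985 between pools of 1 genotype and at 0.979 to 0.983 between genotypes. The first principal component of the 1000 most variable genes took 17.3% of the variance, with knockout pools at −31.1 to −4.67 and wildtype pools at 14.3 to 27.3. No pair of pools of 1 genotype matched within sampling noise.

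Opn4 (chromosome 14, 34590618 to 34600142, minus strand, GRCm38) was lower in every knockout pool. The knockout pools held 1.07, 1.82, 1.15, 1.42 and 1.35 CPM and the wildtype pools 11.8, 11.4, 12 and 11.6 CPM, so that 11.6% of the wildtype level remained. The log2 fold change was −3.10 (SE 0.14; edgeR adjusted p = 1.28e-07), and the exact permutation p of 0.00794 is the smallest that 5 pools against 4 can give. Both Opn4 transcripts fell alike in the TPM table, by 2.31 and 2.23 on the log2(TPM + 0.5) scale. Every library matched its label.

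Loss of melanopsin went with a broad but shallow change of the P4 retina, in which 26 of 32 progenitor and cell cycle genes were lower, and 12 of 19 rod genes, 6 of 18 bipolar cell genes and 5 of 26 glutamate synapse genes were higher. Camera called these 4 lists with a preset correlation, but with an estimated correlation gave an adjusted p = 0.101, 0.227, 0.22 and 0.109. Of 21150 genes tested, 760 differed between the genotypes, 284 higher and 476 lower in knockout (edgeR adjusted p under 0.05), while 3493 had an unadjusted p under 0.05. The median size of the called changes was 0.44 on the log2 scale, and 52 genes changed by at least 2-fold, 34 of them upward. The ranges of both genotypes did not overlap for 265 of the higher and 468 of the lower genes; among all tested genes this held for 8.29%, where 1.59% is given by chance. Without knockout pools 1 and 2, which hold lens transcripts, 486 genes were called and 409 of them were shared with the full set. Without wildtype pool 3, which held little Xist, 638 were called and 562 were shared. The count of higher genes was 153 without wildtype pool 4, 165 without wildtype pool 1 and 158 without knockout pool 2.

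Genes of retinal progenitors and the cell cycle were lower in knockout. Of 32 measured members, 26 were lower and 1 higher (30 lower and 1 higher when adjusted over the list alone), with a median log2 fold change of −0.54. Ccna2, the cyclin of S and G2 phase, fell from 146 ± 8.6 CPM in wildtype to 90.6 ± 4.0 CPM in knockout (log2 fold change −0.69, SE 0.05, adjusted p = 1.37e-05). Cdk1, the kinase that drives entry into mitosis, had a log2 fold change of −0.74, the replication helicase subunit Mcm6 one of −0.67, and the replication clamp Pcna one of −0.55. The other lower members included the replication genes Mcm2, Mcm3, Mcm4, Mcm5 and Mcm7, the mitotic genes Top2a, Mki67, Aurka, Aurkb, Bub1, Plk1 and Cdc20, and the neurogenic factors Atoh7 and Olig2. The members given here without values were chosen after their values were seen. Among the progenitor factors Hes5, Sfrp2, Lhx2, Rax and Neurog2, all named outside the rule, none passed the test (edgeR adjusted p 0.0715, 0.581, 0.0767, 0.239 and 0.174). The list level lay between −0.37 and −0.07 in the knockout pools and between 0.25 and 0.30 in the wildtype pools. Camera gave an adjusted p of 4.22e-37 and fry one of 0.00163, but adjusted p = 0.101 with an estimated correlation. Knockout pools 1 and 2 held lens transcripts and the lowest levels of this list, and without them 22 members were lower, with a median of −0.45. Without wildtype pool 3, 24 were lower.

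**Figure D1:**
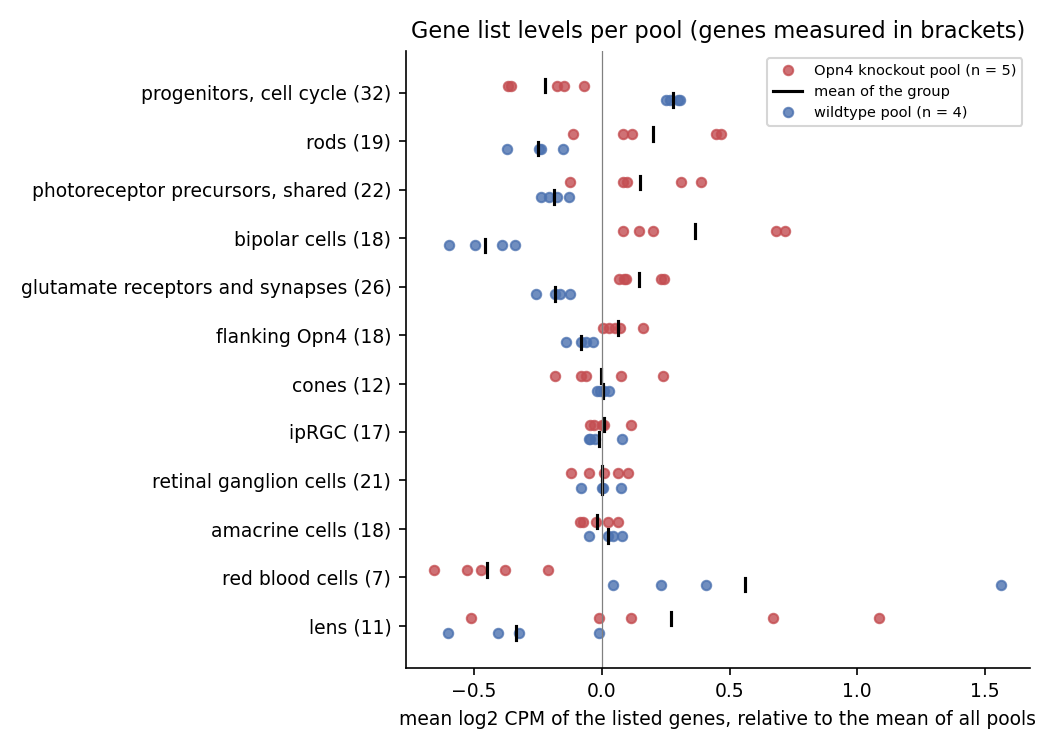
Levels of 12 gene lists in each pool, as the mean log2 CPM of the listed genes relative to the mean of all pools (horizontal axis), with 5 knockout pools in red, 4 wildtype pools in blue and group means as black bars. The progenitor list lies between 0.25 and 0.30 in wildtype and between −0.37 and −0.07 in knockout, while the knockout pools spread from −0.11 to 0.47 for rod genes.

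Rod genes were higher in knockout. Of 19 measured rod genes, 12 were higher and 0 lower (16 higher when adjusted over the list alone), with a median log2 fold change of 0.50. Cnga1 and Cngb1, both subunits of the rod cyclic nucleotide-gated channel, rose from 30.6 ± 3.1 to 54.0 ± 10.5 CPM and from 111 ± 10 to 177 ± 30 CPM (log2 fold changes 0.82 and 0.67; edgeR adjusted p = 0.00247 and 0.00382). Gngt1, the rod transducin gamma subunit, had a log2 fold change of 0.73 and Rp1, an axoneme protein of outer segments, one of 0.65. Nrl, the transcription factor that sets rod fate, rose by 0.29, while Nr2e3, its partner and like it named outside the rule, measured 0.27 without passing the test (adjusted p = 0.073). Nrl lies on chromosome 14 as Opn4 does (55518978 to 55524981). In the authors' deposited table it did not reach a q under 0.05 (q = 0.0788). The rod list had a camera adjusted p of 1.34e-15 and a fry adjusted p of 0.0374, but adjusted p = 0.227 with an estimated correlation. Genes of photoreceptor precursors and genes shared by rods and cones went the same way, with 8 of 22 higher and 0 lower (17 higher when adjusted over the list alone) and a median of 0.28. They included Rdh12 (a retinol dehydrogenase, log2 fold change 0.76), Prph2 (0.45) and Rom1 (0.33), the latter both proteins of outer segment discs. That list had a camera adjusted p of 4.78e-13, a fry adjusted p of 0.0584, and adjusted p = 0.240 with an estimated correlation.

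Knockout pools 1 and 2 stood highest for rod genes, at 0.46 and 0.45 against 0.12, 0.08 and −0.11 in knockout pools 3 to 5 and −0.37 to −0.15 in wildtype. The same pools held the most lens transcripts, with Cryaa (alpha-A crystallin) at 4.65 and 3.28 CPM against 0.0812 to 0.737 CPM in the other pools. Without them, 7 rod genes and 4 of the shared photoreceptor genes were higher, with medians of 0.27 and 0.20 and camera adjusted p of 7.46e-13 and 6.41e-09. Without wildtype pool 3, 8 rod genes and 5 of the shared photoreceptor genes were higher. Cone genes did not change as a group: 0 of 12 passed the test (also 0 when adjusted over the list alone), the median was −0.03, and the camera adjusted p was 0.76. Thrb and Rxrg, nuclear receptors of developing cones, measured 0.18 and −0.16 (adjusted p = 0.202 and 0.230). Without knockout pools 1 and 2, the cone list had a median of −0.12 and a camera adjusted p of 0.032, with 1 gene lower.

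Some bipolar cell genes were higher in knockout, Bhlhe23 and Grm6 among them from low levels. Of 18 measured, 6 were higher and 0 lower (11 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 0.34. Called or not, 13 had a positive and 5 a negative fold change. Bhlhe23, a transcription factor of rod bipolar cells, rose from 0.171 ± 0.088 to 1.45 ± 0.82 CPM (adjusted p = 0.00251). Grm6, the glutamate receptor of ON bipolar cells, rose from 0.0249 ± 0.034 to 1.09 ± 1.0 CPM (adjusted p = 0.00787), Grik1, a kainate receptor of OFF bipolar cells, had a log2 fold change of 0.91 and Prkca, protein kinase C alpha, one of 0.28. The calls of Grik1 and Prkca were lost without wildtype pool 4 and wildtype pool 1, respectively (adjusted p up to 0.0571 and 0.0531). The list had a camera adjusted p of 3.57e-05 and adjusted p = 0.220 with an estimated correlation; its call was lost when genes with a mean CPM under 1 were left out (0.129). Knockout pools 1 and 2, which hold lens transcripts, stood highest (0.68 and 0.72 against 0.08 to 0.20 in the other knockout pools), and without them 2 members were higher, with a median of 0.28 and a camera adjusted p of 0.000865. In gene-summed TPM the call of the list was lost (camera adjusted p = 0.207): 1 of 12 measured members was higher, with a median of 0.11. Among genes of glutamate receptors and synapses, 5 of 26 were higher and 0 lower (8 when adjusted over the list alone), with a median of 0.11. They were Grm6, Grik1, the vesicular glutamate transporters Slc17a7 (0.48) and Slc17a6 (0.20), and the ribbon synapse syntaxin Stx3 (0.35). The call of Slc17a7 was lost without wildtype pool 1 (adjusted p 0.0563) and that of Stx3 without 4 single pools (up to 0.0879). That list had a camera adjusted p of 1.07e-07, a fry adjusted p of 0.0165, and adjusted p = 0.109 with an estimated correlation, and 3 members were higher without knockout pools 1 and 2.

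**Figure D2:**
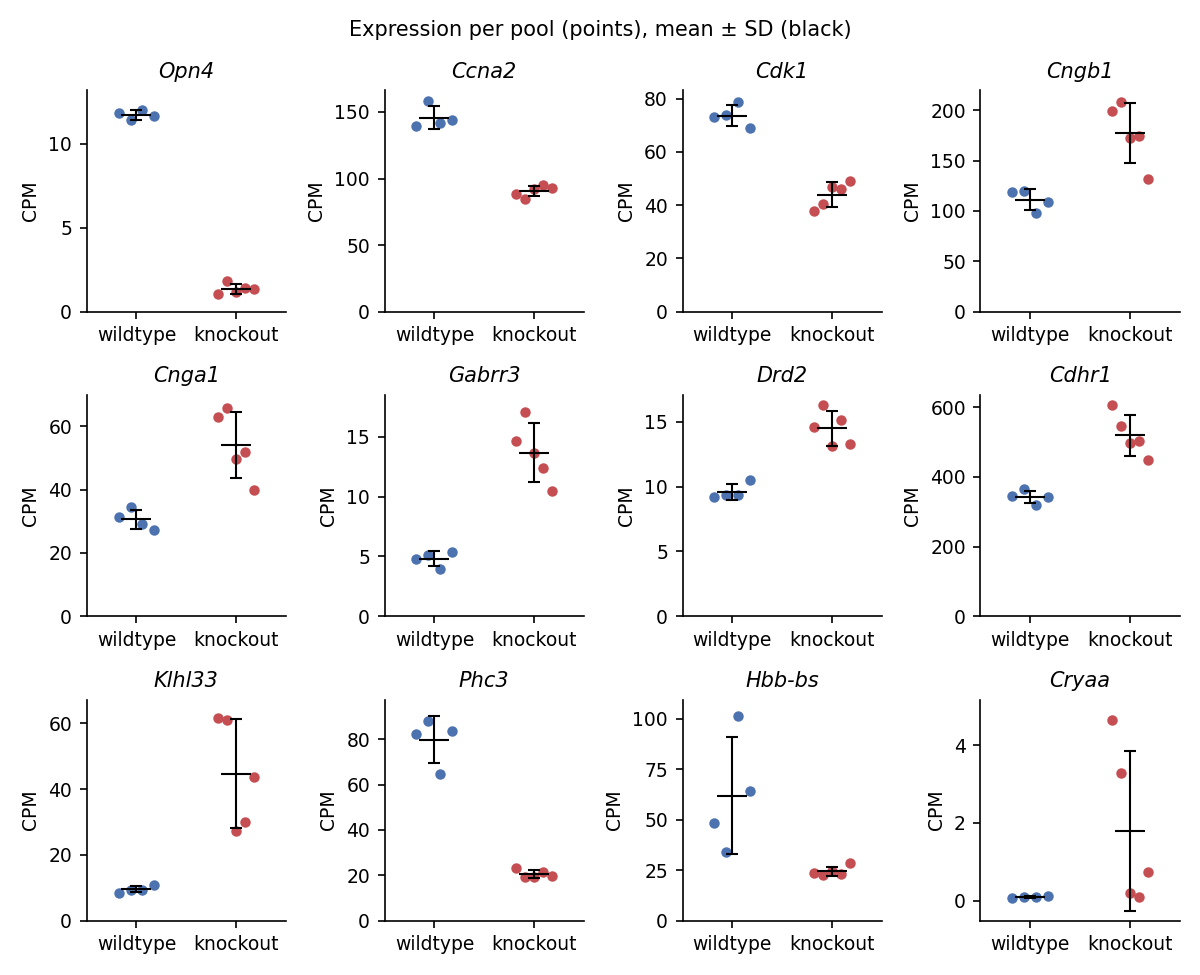
Level of 12 genes in CPM (counts scaled to library size, vertical axis) in 4 wildtype pools (blue) and 5 knockout pools (red), with mean ± SD in black. Opn4 lies at 11.4 to 12 CPM in wildtype and 1.07 to 1.82 CPM in knockout, and Ccna2 falls from 146 ± 8.6 to 90.6 ± 4.0 CPM, while Cngb1 and Klhl33 spread widely among the knockout pools.

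Listed genes that mark ipRGCs or carry melanopsin signals changed little apart from Opn4. Whole retina was measured, so these values do not show whether transcripts within the ipRGCs, or the number of these cells, changed. Of 17 measured genes that mark these cells or carry melanopsin signals, Spon1, an extracellular matrix protein, was higher (log2 fold change 0.18, adjusted p = 0.0341) and none was lower, with 2 higher and 0 lower when adjusted over the list alone, and the camera adjusted p was 0.52. The call of Spon1 was lost without any of 7 single pools (adjusted p up to 0.0905). Plcb4, the phospholipase downstream of melanopsin, measured 0.19 (adjusted p = 0.0564, and 0.0257 without wildtype pool 4). Eomes, a transcription factor that ipRGCs require and a gene named outside the rule, measured 43.5 ± 3.0 CPM in knockout and 43.9 ± 4.1 CPM in wildtype (adjusted p = 0.954). Among 21 second messenger genes of melanopsin and dopamine, none passed the test (1 higher when adjusted over the list alone; camera adjusted p 0.134, and 0.0302 without knockout pools 1 and 2). Of 21 genes of all retinal ganglion cells, Nefh, a neurofilament (0.36), Slc17a6 and Ebf3 (0.18) were higher and none lower, 3 higher also when adjusted over the list alone, with a camera adjusted p of 0.681, and 0.0234 without knockout pools 1 and 2. The calls of Slc17a6 and Ebf3 were lost without 7 and 5 single pools, respectively (adjusted p up to 0.134 and 0.0737).

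Among 18 genes of dopamine synthesis, transport and reception, Drd2 alone passed the test, also when adjusted over the list alone. Drd2, an inhibitory dopamine receptor found on dopaminergic amacrine cells, rose from 9.59 ± 0.61 to 14.5 ± 1.3 CPM (log2 fold change 0.60, SE 0.09, adjusted p = 0.00156), and its call held without any single pool. Th, the enzyme that limits dopamine synthesis and a gene named outside the rule, measured 1.06 ± 0.39 CPM in knockout and 0.959 ± 0.42 CPM in wildtype (adjusted p = 0.881), and Slc18a2, the vesicular monoamine transporter, −0.17 (adjusted p = 0.246). The list had a camera adjusted p of 0.996. Of 17 genes of acetylcholine and retinal wave signalling, Gjd2 (connexin 36, 0.27, adjusted p = 0.0114) was higher and none lower (1 and 1 when adjusted over the list alone; camera adjusted p 0.645), and its call was lost without wildtype pool 4 (adjusted p 0.053).

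In the remaining retinal cell types and pathways single genes changed, and camera called none of their lists over all pools. Of 18 amacrine genes, Ptf1a, which specifies amacrine and horizontal cells, was lower (−0.79, adjusted p = 0.0175), as was Gad2, which makes GABA (−0.29, adjusted p = 0.0302); none was higher, 1 was higher and 4 lower when adjusted over the list alone, and the camera adjusted p was 0.636. The call of Ptf1a was lost without wildtype pool 3 (0.0546) and that of Gad2 without 6 single pools (up to 0.0991). Of 9 horizontal cell genes, Calb1 (calbindin, 0.39) and Prox1 (0.31) were higher and none lower, with 3 higher when adjusted over the list alone, a camera adjusted p of 0.0757 and a fry adjusted p of 0.0292. The call of Calb1 was lost without wildtype pool 4 (0.0542) and that of Prox1 without 3 single pools (up to 0.0898). Camera called that list without knockout pool 2 (adjusted p 0.0454) and without knockout pools 1 and 2 (0.032). Of 18 genes of Müller glia, Rlbp1, the retinaldehyde-binding protein (0.38, adjusted p = 0.000561), and Car14, a carbonic anhydrase (0.70), were higher, and Dapl1 (−0.56) and Id1 (−0.31) lower, with 3 higher and 2 lower when adjusted over the list alone and a camera adjusted p of 0.634, which was 0.0435 without knockout pools 1 and 2; Id1 lost its call without wildtype pool 1 or 3 (up to 0.0557). Of 34 apoptosis and p53 genes, Ccng1 (0.22) and Trp53inp1 (0.23), both p53 targets, were higher and none lower, 3 higher when adjusted over the list alone, with a camera adjusted p of 0.636; each call was lost without 6 single pools. The 23 clock genes held no change, also when adjusted over the list alone (camera adjusted p 0.157). Of 21 immediate early genes, Egr1, which neuronal activity induces, was higher (0.55, adjusted p = 0.0326; 1 when adjusted over the list alone; camera adjusted p 0.24), with a call lost without 6 single pools (up to 0.0741). Among 5 other opsins, 1 was higher and none lower (2 higher and 1 lower when adjusted over the list alone; camera adjusted p 0.867).

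Most red blood cell genes were lower in knockout and 2 of 11 lens genes were higher, both unevenly over the pools. Of 7 red blood cell genes, 5 were lower, also when adjusted over the list alone, with a median of −1.25 (camera adjusted p 2.19e-06, fry 0.0292, adjusted p = 0.220 with an estimated correlation). Hbb-bs, a beta-globin gene, fell from 62.0 ± 29 to 24.4 ± 2.4 CPM, and wildtype pool 3 alone held 101 CPM; without that pool 4 of the genes were lower, with a median of −0.89. Without knockout pools 1 and 2 the list had 2 lower genes and a median of −1.16, and edgeR's robust fit called none of Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2. Hba-a1, Hba-a2, Hbb-bs and Hbb-bt share reads with near-identical copies, so the split between them is uncertain. Of 11 lens genes, Cryaa and Cryab (both alpha crystallins) were higher and none lower, also when adjusted over the list alone (camera adjusted p 0.0242, adjusted p = 0.568 with an estimated correlation), and the list lost its call without knockout pool 1, knockout pool 2 or wildtype pool 2 (adjusted p up to 0.197). Cryaa lost its call without any single wildtype pool (up to 0.117) and Cryab without 7 single pools (up to 0.0943). The lens list level was 1.085 and 0.671 in knockout pools 1 and 2 but −0.512 in knockout pool 4, against −0.601 to −0.012 in wildtype. Of 25 genes of hypoxia and vascular growth, Angpt1, a vascular growth factor, was lower (−0.44, adjusted p = 0.0112) and Hif1a, the hypoxia-inducible factor, higher (0.18, adjusted p = 0.0393, a call lost without 7 single pools, up to 0.11), 4 lower and 3 higher when adjusted over the list alone. That list had a camera adjusted p of 0.0223 and adjusted p = 0.568 with an estimated correlation, and lost its call without wildtype pool 3 or 4 or knockout pool 1 or 4 (up to 0.164).

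No gene was called for endothelium and pericytes (19 measured; camera adjusted p 0.645), astrocytes (10; 0.636), microglia (17; 0.686), pigment epithelium (16; 0.867), skeletal muscle (12; 0.939), fibroblasts (12; 0.926), surface epithelium (7; 0.634) or the sex-linked list (5; 0.62) by edgeR. When adjusted over the list alone, 1 endothelial gene was higher and 1 gene of surface epithelium lower, and none of the other lists named here held a change. Xist, the RNA of the inactive X chromosome, lay at 710 to 943 CPM in the knockout pools and at 830, 1066 and 993 CPM in wildtype pools 1, 2 and 4, but at 14.1 CPM in wildtype pool 3. Ddx3y, a Y-linked gene, was highest in that pool, at 70.1 CPM against 24.7 to 41.3 CPM in the others.

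The largest changes of single genes upward were led by Rnase9 (a secreted RNase-like protein), which measured 3.05 ± 1.2 CPM in knockout and 0.0659 ± 0.049 CPM in wildtype (log2 fold change 5.51, SE 0.50, adjusted p = 0.000104). Klhl33 (a kelch-like protein) rose from 9.53 ± 0.94 to 44.8 ± 16 CPM (2.23, SE 0.23, adjusted p = 0.000217), with 61.7 and 61.2 CPM in knockout pools 1 and 2 and 27.2 to 43.6 CPM in the other knockout pools. Gabrr3, the rho3 subunit of GABA receptors, rose from 4.80 ± 0.61 to 13.7 ± 2.5 CPM (1.51, SE 0.14, adjusted p = 0.000113). Other higher genes were Igkv3-12 (2.26), an immunoglobulin segment of a family with close copies, Gsg1 (1.88), Bsnd (1.45), Cd74 (1.41), the invariant chain of MHC class II, Lrrc66 (1.36), Vmn2r89 (1.08), a pheromone receptor of a family with close copies, Pnp2 (1.08), Lipg (1.05) and Vcam1 (0.96). Among the lower genes were Gli1, a target and effector of Hedgehog signalling, which fell from 11.1 ± 0.66 to 5.25 ± 1.3 CPM (−1.09, SE 0.15, adjusted p = 0.00155), and E2f8, an atypical E2F factor of the cell cycle, which fell from 25.2 ± 2.2 to 13.1 ± 1.8 CPM (−0.94, SE 0.10, adjusted p = 0.000217). The others were Slco2a1 (−1.11), a prostaglandin transporter, the keratin Krt73 (−1.09), Aunip (−1.0), which binds Aurora A, the histone gene Hist1h2af (−0.96), whose reads are shared with similar histone genes, and Alas2 (−1.06) and the globins of red blood cells. Phc3, a Polycomb protein, measured 20.7 ± 1.7 CPM in knockout and 79.7 ± 10 CPM in wildtype (−1.95, adjusted p = 1.28e-07), but its gene-summed TPM went the other way (0.16), so its direction is uncertain. Gene-summed TPM kept the calls of 14 of the 25 genes named for size, Opn4 included. There Pnp2 and Vcam1 measured only 0.41 and 0.28 (limma adjusted p = 0.398 and 0.447). In the authors' deposited table Slco2a1 was −0.31 and Vmn2r89 0.42 (q = 0.627 and 0.396), so the size of these 4 changes is uncertain. Calls were lost without at least 1 single pool for Igkv3-12, Cd74, Lrrc66, Vmn2r89, Vcam1 and Alas2, with adjusted p of up to 0.052, 0.0778, 0.0651, 0.0872, 0.0556 and 0.0825. Besides Opn4, 718 called genes had a mean CPM of at least 1 and no overlap between the genotypes. Of these, 31 were predicted genes or pseudogenes, which the naming rule leaves out. They were led by Gm3375 (2.85) and Gm16867 (−2.61), both of which have near-identical copies and are uncertain.

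Genes on the chromosome of Opn4 were called more often than genes elsewhere. On chromosome 14, 43 of 736 genes were called (5.84%, against 3.55% of 19992 genes elsewhere; odds ratio 1.69, 95% interval 1.2 to 2.32, Fisher's exact p = 0.0024). With genes taken at an unadjusted p under 0.01 instead, the excess did not pass the test (odds ratio 1.24, 0.95 to 1.61, Fisher's exact p = 0.101). Within 20 Mb of Opn4, 21 of 286 were called (7.34% against 3.58%; odds ratio 2.14, 1.29 to 3.36, Fisher's exact p = 0.00213), and 2.03 with Opn4 left out (1.22 to 3.23, Fisher's exact p = 0.00563). At an unadjusted p under 0.01 the odds ratio within 20 Mb was 1.56 (1.04 to 2.27, Fisher's exact p = 0.0233). For genes called with at least a 2-fold change, Opn4 left out, it was 4.46 on chromosome 14 (7 genes, Fisher's exact p = 0.00181). Within 20 Mb it was then 6.31 (4 genes, Fisher's exact p = 0.00491). Of the 18 measured genes fixed as neighbours of Opn4, Cdhr1, Lrit1, Lrit2 and Grid1 were higher and none lower, 7 higher and 1 lower when adjusted over the list alone, with a median of 0.08 (camera adjusted p 0.00116, fry 0.000925, adjusted p = 0.101 with an estimated correlation). Cdhr1 (37077857 to 37098347), a cadherin of photoreceptor outer segments, rose from 343 ± 18 to 520 ± 59 CPM (0.60, adjusted p = 0.000586). Its neighbour Lrit2 (37067929 to 37073743) had a log2 fold change of 0.66 and Lrit1 one of 0.44; Grid1 (34820108 to 35583379), a delta glutamate receptor, had 0.32. The calls of Lrit1 and Grid1 were each lost without 7 single pools (adjusted p up to 0.122 and 0.0982). Rnase9, Klhl33, Pnp2 and Vmn2r89 all lie between 50888582 and 51464172 on this chromosome. By position, 13.2% of tested genes were called between 30 and 40 Mb and 12.4% between 60 and 70 Mb, against 1.3% between 70 and 80 Mb.

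**Figure D3:**
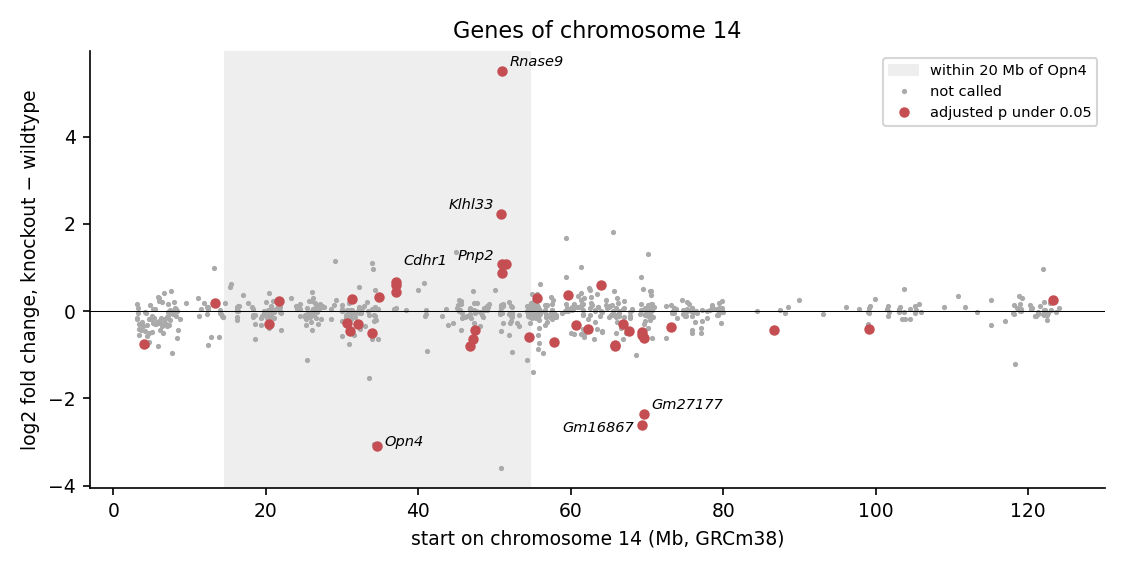
Log2 fold change (knockout minus wildtype, vertical axis) of tested genes along chromosome 14 (start in Mb, GRCm38), with called genes in red and the 20 Mb on either side of Opn4 shaded. Of the tested genes, 13.2% were called between 30 and 40 Mb, 12.4% between 60 and 70 Mb and 1 of only 6 between 80 and 90 Mb; 1 gene with 0 counts in every wildtype pool, whose fold depends on the prior count, is not drawn.

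At the level of transcripts, 86 of 48214 passed the test, 26 higher and 60 lower (limma, adjusted p under 0.05), against 4455 with an unadjusted p under 0.05. They belonged to 81 genes, of which 67 were also called from the counts, and 81 of the 85 transcripts with a tested gene went in the direction of that gene. The lower ones included transcripts of the proliferation genes Pclaf (−0.69), Esco2 (−0.79), Ttk (−0.77), Neil3 (−0.73) and Pbk (−0.78), all named outside the rule. Zfp287, a zinc finger gene, had 1 transcript at 4.00 ± 0.26 TPM in knockout and 0.076 ± 0.10 TPM in wildtype (2.98, adjusted p = 0.0012) and another at 0.024 ± 0.033 and 3.12 ± 0.46 TPM (−2.78, adjusted p = 0.00257), while its gene total was not called (adjusted p = 0.105). Transcripts of Washc2 (3.04) and Mid1ip1 (3.35) were higher, while their gene totals were not called (adjusted p = 0.575 and 0.552). Zfp287, Washc2 and Mid1ip1 were named after their values were seen. The number of called transcripts fell to 9 without wildtype pool 1 or 2, 10 without wildtype pool 4, 11 without wildtype pool 3, and 17, 20, 19 and 45 without knockout pools 2, 1, 4 and 3.

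The authors' deposited table listed 255 of 17433 genes at a q under 0.05, 113 higher and 142 lower in knockout. Of the 249 that were also tested here, 247 had the same sign in the edgeR fit and 187 were called in the same direction; both rest on the same libraries. Across the 15702 genes in both tables, fold changes correlated at a Pearson r of 0.626 and a Spearman rho of 0.723, and 80.3% had the same sign; genes are not independent replicates. In the authors' deposited table, the progenitor list had a median of −0.45 with 9 genes lower, the rod list 0.36 with 4 higher, the shared photoreceptor list 0.21 with 1 higher and the bipolar list 0.24 with 0 higher. Its smallest q upward belonged to Gm6768 (6.40), Gm3375 (2.00), Drd2 (0.56, q = 6.8e-07), Lrit2 (0.63), Cdhr1 (0.56) and Elfn1 (0.44), a synaptic organiser, as log2 values converted from the authors' deposited table. Downward it listed Opn4 (−2.78, q = 1.17e-48), Gm21451 (−6.38), Lrrc63 (−3.14), Gm16867 (−2.26), Atad2 (−0.61), a chromatin ATPase of dividing cells, and Ncapd2 (−0.52), a condensin subunit, in the authors' deposited table. Lrrc63 was not called from the counts (−0.11, adjusted p = 0.967). Gm6768, Gm3375, Gm21451 and Gm16867 have near-identical copies and are uncertain, and from the counts Gm21451 lost its call without 7 single pools (adjusted p up to 0.138).

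**Figure D4:**
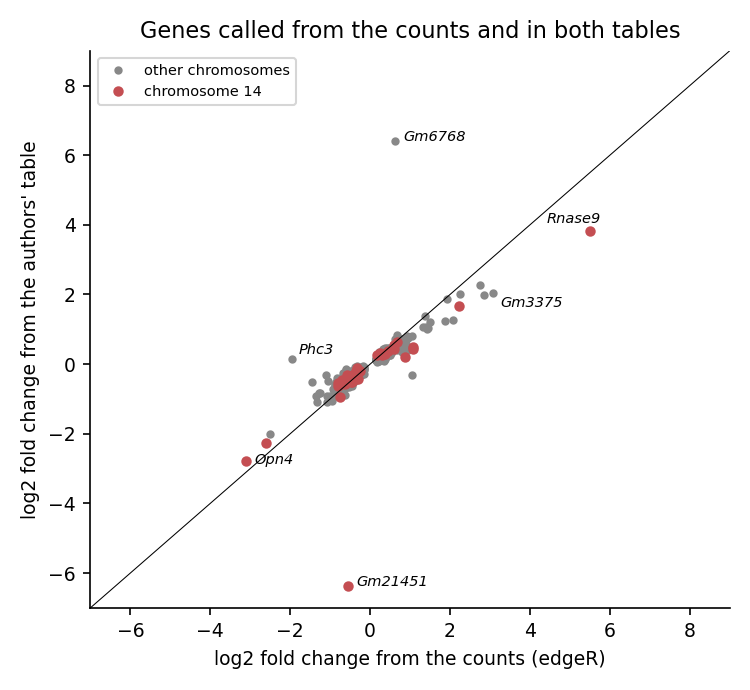
Log2 fold change from the counts (edgeR, horizontal axis) against that in the authors' deposited table (vertical axis, converted to knockout minus wildtype) for the 721 genes called from the counts and present in both, with chromosome 14 in red and the line of equality. Of these, 719 share their sign, and Gm6768, Gm21451 and Phc3 lie farthest from the line among the labelled genes; 1 gene with 0 counts in every wildtype pool is not drawn.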

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

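The tests of single outlying pools were fixed before the values were seen. Within each genotype the highest and the lowest pool were compared with the rest for 354 groups of values, and in 18 of them (5.1%) a pool stood apart by more than Dixon's 95% critical value; chance gives about 1 in 20. The number is thus about what chance gives, and no explanation is offered for single genes other than Xist.

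Xist stood apart in wildtype pool 3, at a log2 CPM of 3.82 against 9.70 to 10.1 in the other wildtype pools. Wildtype pool 3 also held the highest level of the Y-linked gene Ddx3y among all pools. Both values are what a pool of male pups alone would give, although the labels do not give the sex. In that same pool Dapl1 was high (5.68 against 5.36 to 5.37), as was Pcna (7.91 against 7.77 to 7.78), while Mmrn2 (0.66 against 0.80 to 0.81), Ttn (1.64 against 2.27 to 2.38) and Atad2 (5.37 against 5.62 to 5.66) were low. Wildtype pool 4 was far from the rest for Prph2 (8.59 against 8.64 to 8.65), Drd2 (3.40 against 3.20 to 3.23) and Egr1 (3.18 against 3.67 to 3.76), and its Drd2 level still lay below every knockout pool. Wildtype pool 2 was far from the rest for Gsg1 (−0.88 against −1.12 to −1.08) and Lrrc66 (−1.81 against −0.42 to −0.39).

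Among the knockout pools, Rlbp1 was low in pool 1 (7.84 against 7.99 to 8.04), Trp53 in pool 3 (5.60 against 5.68 to 5.70) and Ddx3y in pool 4 (4.62 against 5.19 to 5.37), and Col6a2 was high in pool 5 (4.15 against 3.81 to 3.86). Knockout pool 4 also had the lowest list levels of acetylcholine and retinal wave genes (−0.073 against 0.028 to 0.054), of surface epithelium (−0.37 against −0.01 to 0.06) and of sex-linked genes (−0.20 against 0.05 to 0.11).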

How the results depend on the processing

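The alternatives without knockout pools 1 and 2, without the wildtype pool with little Xist, without chromosome 14, with protein-coding genes alone and with camera on gene TPM were chosen after seeing the data. Over 4002 settings of 145 named genes, 3636 gave the same direction and side of the threshold, 309 lost a call, 56 gained one and 1 reversed: Phc3 measured 0.158 in gene-summed TPM. Over 600 settings of the lists, 565 were the same, 28 lost a call, 7 gained one and 0 reversed. The count of called genes was 1502 with DESeq2, 1214 with 1 surrogate variable, 330 in gene TPM, 177 for a change of at least 1.2-fold, 1201 at an adjusted p under 0.1, 486 without knockout pools 1 and 2, and 549 to 936 under the other settings. Leaving out each pool gave 524 to 859, with 284 higher genes becoming 158 without knockout pool 2, 165 without wildtype pool 1 and 153 without wildtype pool 4. Of the 25 genes named for the size of their change, Opn4 included, gene TPM kept 14 and the other settings 19 to 25. Opn4 ranged from −3.23 to −3.03 over single pools left out. The authors' deposited table held 255 genes at a q under 0.05 and 440 at a q under 0.1, and 28 of the 255 had an absolute effect of at least 0.5 in natural log units. The odds ratio for chromosome 14 was 1.24 at an unadjusted p under 0.01 (Fisher's exact p = 0.101), and that within 20 Mb of Opn4 was 1.56 (Fisher's exact p = 0.0233). Except where fewer pools, genes or a changed threshold were the setting itself, the cause was not tested.

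With an estimated correlation 0 lists were called by camera (5 at an unadjusted p under 0.05, and 7 called by fry), with adjusted p of 0.227 for rods, 0.24 for photoreceptor precursors, 0.22 for bipolar cells and red blood cells, 0.101 for progenitors and for the genes flanking Opn4, 0.109 for glutamate synapses, and 0.568 for hypoxia and lens; other settings called 7 to 12 lists. Fry gave 0.0584 for photoreceptor precursors, 0.267 for hypoxia and lens, and 0.0292 for horizontal cells. Without knockout pools 1 and 2, adjusted p was 0.032 for cones and horizontal cells, 0.0234 for ganglion cells, 0.0435 for Müller glia, 0.0302 for second messengers, 0.217 for hypoxia and 0.294 for lens. Bipolar cells lost their call at a mean CPM of at least 1 (0.129) and in gene TPM (0.207), and lens in gene TPM (0.0526) and with a surrogate variable (0.0848). Hypoxia lost it with Y-linked expression as a covariate (0.151), with a surrogate variable (0.0907) and without the wildtype pool with little Xist (0.164). Over single pools left out, adjusted p ran from 0.0454 to 0.139 for horizontal cells, 0.000617 to 0.164 for hypoxia and 0.00222 to 0.197 for lens.

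Against 86 called transcripts with all pools, 9 to 102 were called over single pools left out, with 102 without knockout pool 5 and at most 45 without any other. With the replicate number as a block on pools 1 to 4, edgeR called 915 genes, against 859 in the same 8 pools without the block, camera called 9 lists, Opn4 measured −3.12 and 2 transcripts were called. The pools of a number share only that number, since deviations of pools with the same number correlated at 0.002, −0.031, 0.006 and −0.030 across genes. Depth was 65.5 M to 86.1 M counts per pool and the common biological coefficient of variation 0.149, so depth limits mainly the genes of low counts.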

Other observations

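The tests of lens, sex mix, list genes within genotypes, linked alleles and other windows, shared reads, copies and other splits were chosen after the result was seen, unlike the test over all genes within genotypes and that of pseudogene parents.

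Of 15 called pseudogenes with a near-identical parent gene, 8 had the sign of the parent's fold change and 7 the opposite sign. Hmgb2, a chromatin protein abundant in dividing cells, was lower in knockout (log2 fold change −0.55, edgeR adjusted p = 0.000354), and its pseudogenes Gm4739 (−0.53), Gm13167 (−0.68) and Gm13237 (−0.65), which are 99.7, 98.8 and 98.7% identical to it, were lower too. Rbm3, an RNA-binding protein that cold induces, was lower (−0.41, adjusted p = 0.000501), together with its copy Gm10156 (−0.60). The histone genes Hist1h2ai and Hist1h2ao, which S phase cells express, were lower (−0.63 and −0.73), as were their copies Hist1h2aj and Gm11336 (−0.80 and −0.95). Opposite signs were measured for Gm12918 (1.29) and Gm15710 (1.06) against Rpl13 (−0.22), Gm8210 (−2.51) and Gm15454 (−1.73) against Rpl29 (0.36), Rps26-ps1 (1.88) against Rps26 (−0.21), Gm3375 (2.85) against Psmb5 (−0.28) and Gm6768 (0.63) against Ncoa4 (−0.04). Of these parents only Rpl13 was itself called. Near-identical genes can share reads, so the counts of each are uncertain, and these genes were named after their values were seen.

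Progenitor genes were lower and rod genes higher in knockout. Of 100 splits of the 9 pools, only the real split called 760 genes or more, the highest other calling 401. Only the real split had a strongest list, or a progenitor list, with a camera minus log10 p as large as 37.85 (highest other 31.7). Both of these highest other values came from knockout pools 1 to 4 set against knockout pool 5 and all wildtype pools. That split keeps most of the genotype contrast. Among the drawn splits with 2 wildtype pools on either side, at most 7 genes were called, with a progenitor minus log10 p of at most 5.39. Chance is thus an unlikely source of the gene count and of the progenitor result, but it is not excluded. Not every possible split was drawn, and the progenitor list had a camera adjusted p = 0.101 with an estimated correlation. The rod list was not itself set against other splits. For progenitors, lens carried over in knockout pools 1 and 2 and a different mix of sexes were argued against as the whole cause, since the median of −0.54 stayed at −0.45 without these pools and at −0.531 with Y-linked expression as a covariate, and for rods the sex mix was argued against likewise (0.468 against 0.50). Lens carry-over cannot be told apart for rods by this test. Knockout pools 1 and 2 also stood highest for rod genes, so leaving them out lowers the rod median whatever the cause. Without these pools the rod median was 0.273, within the standard error between pools (0.085) of the bound of 0.252 set for this test. Without them 7 rather than 12 rod genes were called, while the bipolar median was 0.28 against 0.34. A difference in developmental stage between pools for a reason other than genotype, such as litter or hour of birth, cannot be told apart either. Over all genes the first component within each genotype correlated with the fold change at only 0.071, which had been predicted to speak against it. Genes outside the pattern dilute that value. Over the 51 progenitor and rod genes the correlation was 0.405 in wildtype and 0.883 in knockout. That value decides nothing either, because the genes were taken from lists already seen to change in opposite directions. Both lists also lay on opposite sides of that component in each genotype. An effect of melanopsin loss itself stays open, as no test here parts it from these.

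Called genes gathered on chromosome 14 around Opn4. With Opn4 left out, the odds ratio of a call within 20 Mb was 2.03 (95% interval 1.22 to 3.23), and 3 of 221 overlapping windows of that width on other chromosomes (1.36%; up to 2.32, on chromosomes 2 and 10) reached it, which is in line with linked alleles of another mouse strain carried along with the targeted locus. That does not single them out, since windows elsewhere reached it with no targeted locus. By stretches of 10 Mb, 13.2, 6, 6 and 12.4% of genes were called from 30 to 70 Mb. From 0 to 30 Mb the shares were 1.4 to 2.4%, and from 70 to 80 Mb 1.3%, while stretches beyond 80 Mb held at most 24 tested genes. The calls between 60 and 70 Mb lie outside the window but do not argue against linked alleles, whose reach is not known. Reads shared between copies cannot be told apart as a contributor, because among 7 called genes with at least a 2-fold change only 4 had a TPM test, of which 75% (3 genes: Klhl33, Rnase9 and Gm16867) kept their direction with at least a 1.5-fold change. For Cdhr1, Lrit1 and Lrit2, which lie within 2.5 Mb of Opn4 while Drd2 and Gabrr3 lie on chromosomes 9 and 16, linked alleles and loss of melanopsin may both contribute, and the design holds no second allele that would part them. The rise of Cdhr1, a photoreceptor gene, by 0.60 is also near the rod list median of 0.50. Whatever raised the rod genes may therefore contribute to it too.

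Some genes differed between the count and TPM tables. Of 711 called genes measured in both, 9 had fold changes at least 1 apart on the log2 scale, and 6 of these had a near-identical copy, against 33 of the other 702 (odds ratio 39.8, Fisher's exact p = 1.38e-06). A different treatment of reads that match several copies, in the counts and by kallisto, may thus account for part of them, such as Gm6768, which is 99.9% identical to Ncoa4 (chromosome 14, 32159865 to 32179855) and measured 0.63 in the counts but 4.71 in TPM. The pseudocount of the TPM scale shrinks low genes: by the ratio of mean TPM, Rnase9 (6.92 against 0.185 TPM, log2 ratio 5.22) and Gm3375 were no longer apart from the counts, Igkv6-20 was left out as it had 0 TPM in wildtype, Gm8210 and Hist1h2an came apart, and 6 of the 8 genes then apart had a copy (against 32 of 702; odds ratio 61.4, Fisher's exact p = 4.1e-07). Phc3 (−1.95 in the counts, 0.16 in TPM) and Igkv3-2 had no such copy, and their difference stays open.

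It was tested whether called pseudogenes on other chromosomes take reads from strain variants of chromosome 14 parents, as the pairs of Gm6768 with Ncoa4 and of Gm3375 with Psmb5 (98.9% identical; chromosome 14, 54614119 to 54618022) may suggest. Leaving out this pair of pseudogenes, 0 of 13 called pseudogenes and 30 of 1240 uncalled ones had their closest gene on chromosome 14, an odds ratio of 0 (95% interval 0 to 13.9), which decides nothing with so few called.

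The number of called lists and transcripts was also set against other splits. At least 9 lists were called in 26 of 100 splits, with up to 15 in another split, so chance cannot be excluded for that number. Some of these splits keep most of the genotype contrast, but those with 2 wildtype pools on either side also called up to 14. At least 86 transcripts were called in 2 of 100 splits, so a count this large is rare, but the split of knockout pools 4 and 5 with wildtype pools 2 and 3 against the rest called 112.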
